A study of Sorghum bicolor with 12 samples.

How the data were processed

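The series measured messenger RNA in roots of mature sorghum plants (Sorghum bicolor) by RNA sequencing. The near-isogenic line NIL-bri1-72 carries a base change, from an EMS-mutagenized family, in the extracellular part of the brassinosteroid receptor SbBRI1. NIL-WT-72 is the line without it. Each line was kept watered or held at 30% of field capacity. Per the labels' protocols, libraries were made with a stranded mRNA kit and sequenced as paired reads. The series design gives 3 biological replicates per line and regime, hence 12 libraries in 4 groups. Groups and replicate numbers were taken from the sample titles.

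The authors deposited 1 table of raw read counts per gene identifier. It lists 20818 identifiers and 12 libraries, with no column outside these samples. FastQC 0.11.2, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 1.6.2 are named in the submitters' processing notes. Their parameters, the genome build, the annotation and the strand setting of the counting are not given in the sources used here, so a gene and an antisense partner may share reads. The deposited counts summed to between 18640601 and 33296273 per library. The smallest count in a library was 8 to 13, and it equalled 0.379 to 0.429 CPM, the count scaled to a common library total. No library had a 0. The deposited counts thus list only genes at or above about that level in all 12 libraries, and the rule behind this is not given in the sources used here. A gene that is silent in 1 line or 1 regime is not analysed here.

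The identifiers are not paired with gene names in the table. Of the 20818 identifiers, 0 matched an entry of the 32945-gene RefSeq table of sorghum used here. The 36 gene lists that had been fixed as patterns on product descriptions were therefore not applied, no list test was run, and no gene is named by function. SbBRI1 itself is not reported for the same reason. Checks of GC content or gene length would be void, because no gene had a value. The digits before the G of an identifier are taken as its chromosome and those after it as its order along that chromosome, by the numbering convention of these sorghum gene models, which was not checked against a genome. Identifiers on unplaced scaffolds numbered 16.

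Counts were tested with edgeR 4.0.16 in R 4.3.3. Its filterByExpr rule kept 20818 genes, libraries were scaled by TMM, and a quasi-likelihood model with 4 group means was fitted to all 12 libraries without a replicate block. The biological coefficient of variation was 0.209 and the prior degrees of freedom were 3.12. Benjamini-Hochberg adjusted p-values below 0.05 over all genes tested were called. Standard errors of log2 fold changes were the absolute log2 fold change divided by the square root of the F statistic. The planned contrasts were drought against water in each line, NIL-bri1-72 against NIL-WT-72 in each regime, and their interaction, meaning the drought effect of NIL-bri1-72 minus that of NIL-WT-72. Contrasts averaged over the other factor were added after the data had been examined. The groups, the test, the first 5 contrasts and the first set of alternative settings were chosen before the data were examined.

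Named genes followed a fixed rule: the largest changes in each direction among called genes with at least 10 CPM in 1 of the groups compared and no overlap between the replicates of the sides compared. Its condition on product descriptions could not be applied, and without names it allowed 2 identifiers per direction and comparison. The same rule was applied to the averaged contrasts, for which it had not been written. Genes named outside it are marked as chosen after their values were seen.

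A drought index was computed per library from log2 CPM values with a prior count of 2. The 300 genes with the lowest p-values for drought in the other line were used, and the mean of those that had fallen was subtracted from the mean of those that had risen. The fold changes that rank the genes and the libraries scored thus share no library, although the spread behind the p-values was estimated over all 12. A pooled index used the genes called for drought averaged over both lines. Both indices were added after the data had been examined. Index comparisons used exact permutation tests, two-sided. Principal components were computed on the same log2 CPM values.

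On simulated counts with the means, library sizes and dispersions of these data, 50 of the 20818 genes were changed at each of 4 fold sizes. For drought in NIL-WT-72, 8% of genes changed 1.5-fold were recovered, 50% of those changed 2-fold, 96% of those changed 4-fold and 96% of those changed 8-fold. The shares were 38%, 80%, 98% and 100% for drought averaged over both lines, and 0%, 26%, 76% and 92% for the interaction. False calls numbered 3 of 128, 8 of 166 and 7 of 104. Simulated genes varied independently, whereas the real libraries deviate on many genes at once, and these shares do not cover such deviations. The search for chromosome windows was tested on 20000 independent simulated values with a segment of 100 genes shifted by 1.5 SD, and found 20 of 20 such segments. Weaker segments were not simulated.

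The first set of alternative settings was DESeq2 size factors within edgeR, no filter, a filter of at least 5 CPM in 3 or more libraries, DESeq2 1.42.0, limma 3.58.1 with voom, an added limit of at least 1 on the log2 fold change, only the libraries compared, the replicate number as a block, and each of the 12 libraries left out. Alternatives added later were voom with library quality weights, the block within the 6 libraries compared, and a fit without 2 NIL-WT-72 libraries. DESeq2 gave no adjusted p for 49 genes for drought in NIL-WT-72 and for 1259 in NIL-bri1-72. Whether replicate numbers pair the samples was checked by correlating deviations from group means. For NIL-bri1-72 in water and in drought the same-number correlations were 0.360, 0.190 and 0.125, all above 0.1. The numbers were therefore treated as pairing those 6 libraries, on the data alone. The bound of 0.1 is not a test, so pairing is not established in either line. No replicate pair was a duplicate: the chi-square statistic per degree of freedom was 16.4 to 67.2 within groups. Other computations and figures used Python 3.11.15 with SciPy 1.17.1 and matplotlib 3.10.9.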

Results

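Root transcriptomes of NIL-bri1-72, which carries a base change in the extracellular part of the brassinosteroid receptor SbBRI1, and of its wild-type sister NIL-WT-72 were compared in watered plants and in plants at 30% of field capacity. The receptor perceives brassinosteroids, plant steroid hormones that control growth. The stated purpose was to find early transcriptional targets of SbBES1, a transcription factor that acts downstream of the receptor, in drought. Each of the 4 groups held 3 libraries. The total count was 26385468, 18640601 and 23170691 for NIL-WT-72 in water and 29382825, 31014782 and 26726791 for NIL-WT-72 in drought. It was 33296273, 25454657 and 24406967 for NIL-bri1-72 in water and 25515363, 30841591 and 32109287 for NIL-bri1-72 in drought. Counts were tested for 20818 genes that had been detected in all 12 libraries. The table carries identifiers only, so genes are given by identifier and chromosome and are not assigned a function.

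Libraries separated by water regime on the first principal component, which held 28.3% of the variance. On it the 6 watered libraries lay between -46.4 and -6.65 and the 6 droughted libraries between -1.56 and 40.2. NIL-WT-72 drought replicate 3 (-0.00216) and NIL-bri1-72 drought replicate 1 (-1.56) lay nearest to the watered libraries. The second component held 18.9% and set apart NIL-WT-72 water replicate 1 at 61.8, with NIL-WT-72 drought replicate 3 next at 23.2, while the other 10 libraries lay between -19.4 and 0.634. The root-mean-square deviation of a library from its group mean was 0.396 log2 units for NIL-WT-72 water replicate 1 and between 0.183 and 0.339 for the other 11 libraries.

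**Figure D1:**
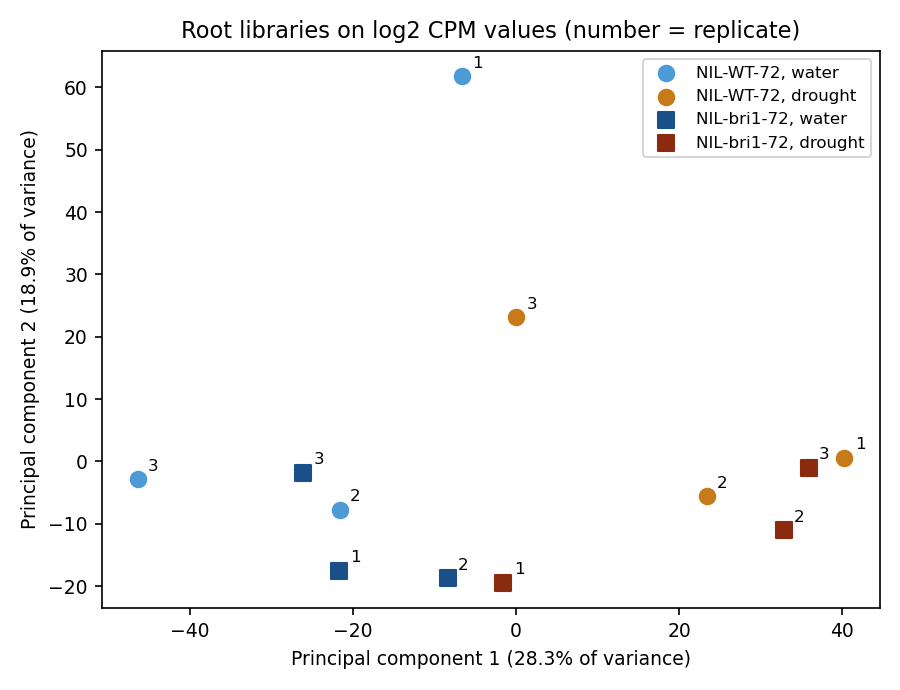
Principal components 1 (28.3% of the variance, horizontal) and 2 (18.9%, vertical) of log2 CPM values, with 1 point per library, coloured by regime and line and numbered by replicate. Watered libraries lie at or below -6.65 on component 1 and droughted libraries at or above -1.56, and NIL-WT-72 water replicate 1 stands apart at 61.8 on component 2.

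The response of wild-type roots to drought was compared first. In NIL-WT-72, 3 genes changed and all 3 fell, out of 20818 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Sobic.009G004900 on chromosome 9 fell from 45.1 ± 18.9 CPM in water to 3.48 ± 1.48 CPM in drought (SD, n = 3), a 13.0-fold decrease. Its log2 fold change was -3.70 (SE 0.44, edgeR adjusted p = 0.0354). Sobic.005G161100 on chromosome 5 fell from 11.4 ± 3.12 to 0.911 ± 0.615 CPM, with a log2 fold change of -3.65 (SE 0.45, edgeR adjusted p = 0.0354). That log2 fold change was -4.31 without NIL-WT-72 drought replicate 3. Without drought replicate 2 it was -3.28 (edgeR adjusted p = 0.175). In drought replicate 2 the count of Sobic.005G161100 was 12, the smallest count in that library, so this value lay at the floor of the deposited counts. The remaining called gene was more abundant and fell from 363.9 ± 20.8 to 108.8 ± 8.09 CPM, a log2 fold change of -1.74 (SE 0.19, edgeR adjusted p = 0.0264). All 3 drought replicates of NIL-WT-72 lay above or below all 3 watered replicates for 12.3% of genes, 1389 upward and 1175 downward, where chance gives 10%.

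The count in NIL-WT-72 depended on the test and on single libraries. An unadjusted p below 0.05 was reached by 1968 genes, 9.45% of those tested, where chance gives a share of 0.05. DESeq2 called 305 genes, 126 higher and 179 lower, which included the 3 genes called by edgeR, and limma voom called 1. Leaving out 1 library moved the edgeR count between 0 and 55. It was 16 without NIL-WT-72 water replicate 1, 55 without NIL-WT-72 drought replicate 3 and 0 without either of the other droughted NIL-WT-72 libraries, without water replicate 3 or without NIL-bri1-72 drought replicate 2. It was 1 without NIL-WT-72 water replicate 2 and 5 without NIL-bri1-72 water replicate 1 or drought replicate 1.

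The same comparison in the mutant line asked how roots with the altered receptor respond. In NIL-bri1-72, 0 genes passed the edgeR threshold, with a lowest adjusted p of 0.0638. An unadjusted p below 0.05 was reached by 1518 genes, 7.29% of those tested, where chance gives a share of 0.05. DESeq2 called 202 genes, 91 higher and 111 lower, and limma voom called 0. Sobic.005G161100 was at 12.3 ± 3.51 CPM in water and 1.29 ± 0.360 CPM in drought (SD, n = 3), a log2 fold change of -3.25 (SE 0.43, edgeR adjusted p = 0.0638). For Sobic.009G004900 the means were 27.0 and 3.41 CPM and the log2 fold change was -2.99 (edgeR adjusted p = 0.0760). The third gene called in NIL-WT-72 had a log2 fold change of -1.31 here (edgeR adjusted p = 0.0706). With the replicate number as a block shared by both lines the NIL-bri1-72 count was also 0. Left-out libraries moved it between 0 and 14, with 14 without NIL-WT-72 drought replicate 3, 8 without NIL-bri1-72 drought replicate 2, 4 without NIL-bri1-72 drought replicate 1 and 1 without NIL-bri1-72 water replicate 1.

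Drought averaged over both lines, a contrast added after the data had been examined, changed 266 genes by edgeR, 109 higher and 157 lower. All 266 had the same sign in each line, which selection on the averaged effect favours. The median log2 fold change was 0.89 for the genes that rose and -1.15 for those that fell, and 44 rose and 95 fell by at least 1 on the log2 scale. Among the genes that rose, Sobic.003G292400 on chromosome 3 was at 2.93 ± 0.973 CPM in water and 29.5 ± 9.81 CPM in drought in NIL-WT-72, and at 2.01 ± 1.20 and 20.01 ± 12.3 CPM in NIL-bri1-72 (SD, n = 3). Its averaged log2 fold change was 3.31 (SE 0.42, edgeR adjusted p = 0.0102). Sobic.003G397400, also on chromosome 3, rose by 2.75 on the log2 scale (SE 0.34, edgeR adjusted p = 0.00967). It was at 1.39 ± 0.702 CPM in water and 12.2 ± 4.01 CPM in drought in NIL-WT-72, and at 1.42 ± 0.677 and 7.29 ± 2.86 CPM in NIL-bri1-72 (SD, n = 3).

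The largest decrease among the genes named for this contrast was that of Sobic.006G011900 on chromosome 6, with an averaged log2 fold change of -5.41 (SE 0.56, edgeR adjusted p = 0.00427). It was at 102.2 ± 25.3 CPM in water and 1.36 ± 0.959 CPM in drought in NIL-WT-72 (SD, n = 3), where its log2 fold change was -6.24 (edgeR adjusted p = 0.0625), and -6.97 without NIL-WT-72 drought replicate 3 (edgeR adjusted p = 0.0337). For drought in NIL-WT-72 the gene passed the threshold under 9 of 23 alternatives, with adjusted p up to 0.406 over all of them. In NIL-bri1-72 it was at 84.6 ± 95 CPM in water, where replicate 2 reached 194.3 CPM and the other replicates 29.5 and 30.0 CPM, and at 3.52 ± 0.662 CPM in drought (SD, n = 3, edgeR adjusted p = 0.124). Without NIL-bri1-72 water replicate 2 the log2 fold change of Sobic.006G011900 was -4.66 averaged and -3.08 in NIL-bri1-72, in place of -4.58 there. Sobic.005G161100 fell by 3.45 on the log2 scale (SE 0.31, edgeR adjusted p = 0.00162). Sobic.006G011900, Sobic.005G161100, Sobic.003G292400 and Sobic.003G397400 stayed past the threshold under each of the 21 alternatives run for this contrast. DESeq2 called 1023 genes, which held all 266. The edgeR count moved by more than 1.5 times whichever library was left out. It was 41 without NIL-bri1-72 drought replicate 3, 45 and 46 without NIL-WT-72 drought replicates 1 and 2, and 70, 94 and 90 without NIL-bri1-72 water replicates 1, 2 and 3. It was 110, 115 and 132 without NIL-WT-72 water replicates 2 and 3 and NIL-bri1-72 drought replicate 2. It rose to 530, 565 and 695 without NIL-WT-72 drought replicate 3, NIL-WT-72 water replicate 1 and NIL-bri1-72 drought replicate 1.

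**Figure D2:**
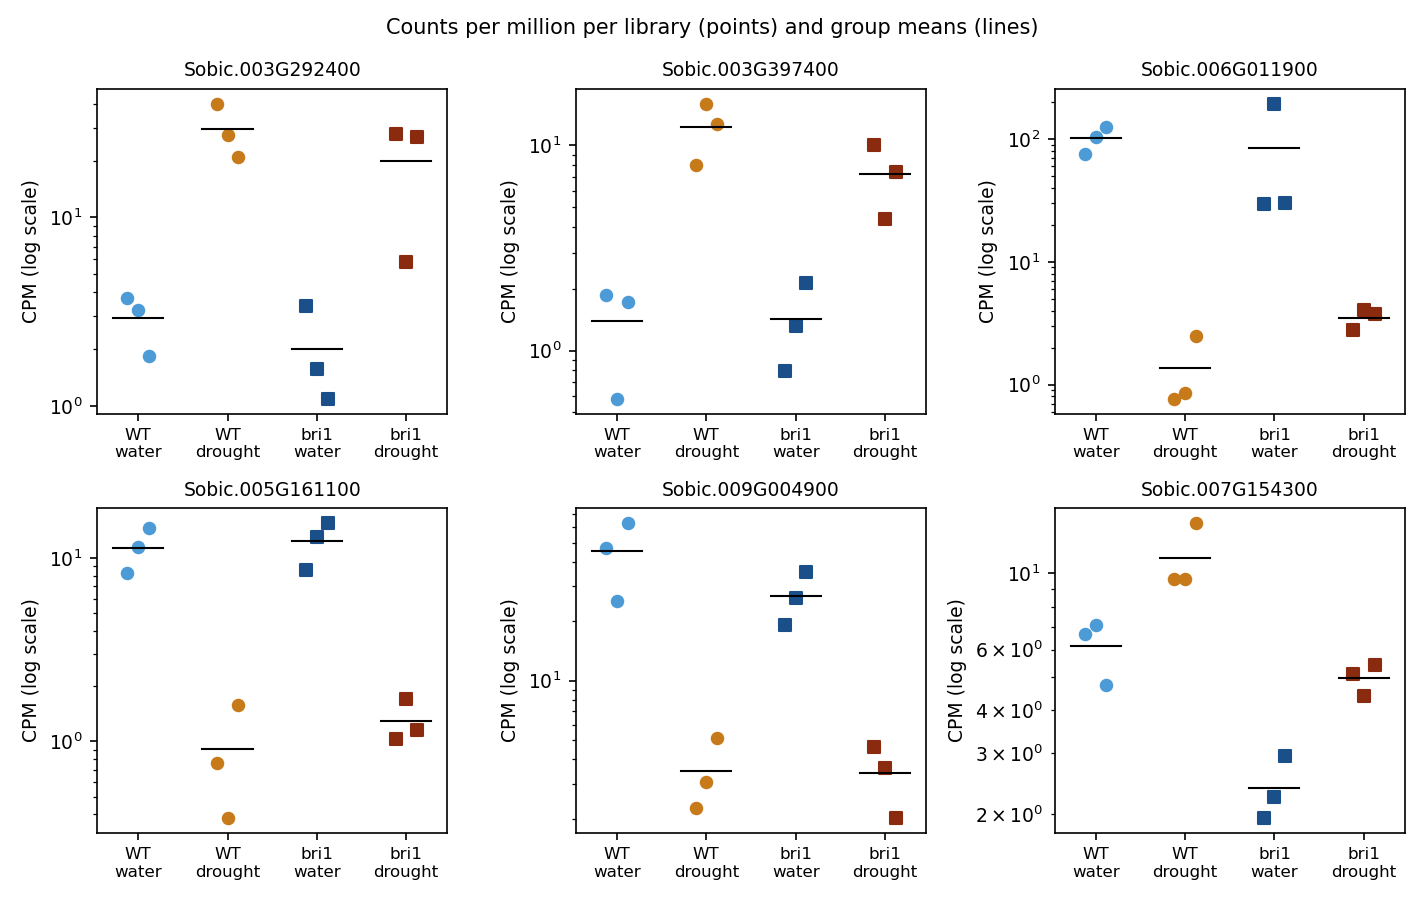
CPM on a log axis for 6 genes, with 1 point per library and a line at each group mean (n = 3 per group). Sobic.003G292400 and Sobic.003G397400 were higher in drought in both lines, Sobic.006G011900, Sobic.005G161100 and Sobic.009G004900 were lower in drought in both lines, and Sobic.007G154300 was lower in NIL-bri1-72 than in NIL-WT-72 in both regimes.

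By chromosome, the drought-called genes made up 2.12% of the 1131 tested genes of chromosome 5 and 1.98% of the 1113 of chromosome 8. They made up 0.776% of the 2450 of chromosome 4 and 0.936% of the 3738 of chromosome 1. The share over the 10 chromosomes was 1.27%, that is 265 of 20802 genes. The shares differed more than in shuffled positions (permutation test with 10000 shuffles, p = 0.0169). With each run of adjacent called genes counted once, which left 255, the difference no longer passed (permutation p = 0.102).

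Whether both lines responded alike was examined across all genes and by the interaction. The drought log2 fold changes of the lines share no library and correlated across genes with Pearson r = 0.607 and Spearman rho = 0.489, where genes are not independent replicates. The standard deviation of these log2 fold changes was 0.394 in NIL-WT-72 and 0.343 in NIL-bri1-72, and this order turned without NIL-bri1-72 drought replicate 1, at 0.394 and 0.436. No gene was called by edgeR in both lines, since none passed in NIL-bri1-72. DESeq2 called 38 genes higher and 79 lower in both lines and 0 in opposite directions, against 0.582 and 0.993 for independent lists of those lengths.

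**Figure D3:**
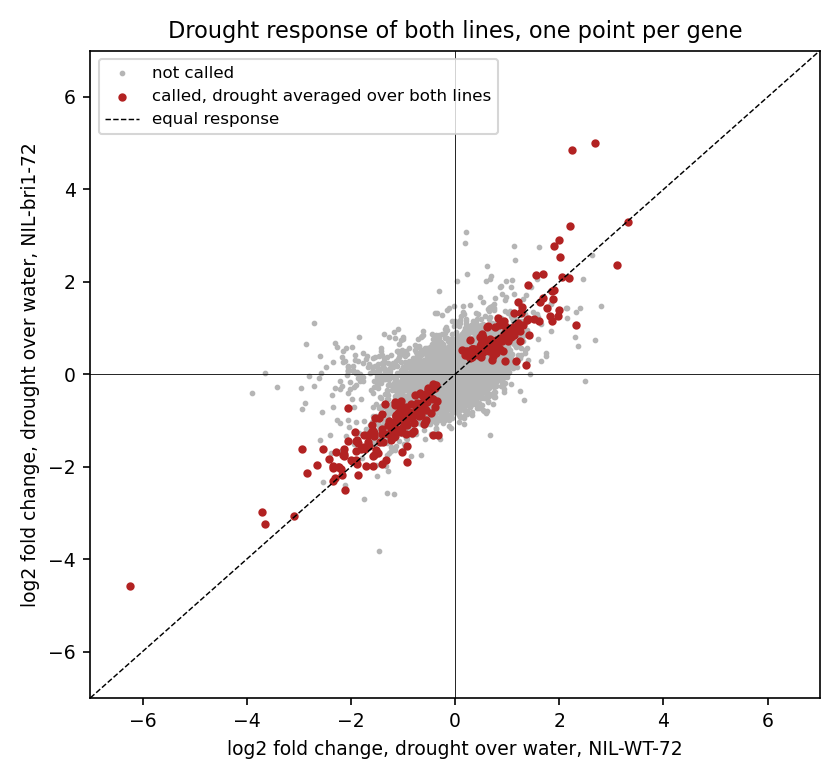
Log2 fold change of drought over water in NIL-WT-72 (horizontal) and NIL-bri1-72 (vertical), 1 point per gene, with the 266 genes called for drought averaged over both lines in red and a dashed line at equal response. Over all genes r was 0.607, and the called genes lie in the quadrants of equal sign, where selection on the averaged effect tends to place them.

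The interaction tested whether the drought effect differed between the lines, and 0 genes passed by edgeR, by DESeq2 or by limma voom. An unadjusted p below 0.05 was reached by 232 genes in edgeR, 1.11% of those tested, and by 283 genes in DESeq2, 1.36%. Both shares lie below the 0.05 that chance gives. Among the 266 drought genes the median log2 fold change, taken in the direction of the averaged effect, was 1.08 in NIL-WT-72 and 1.03 in NIL-bri1-72. In that direction the log2 fold change was smaller in NIL-bri1-72 for 155 of these genes, and the lowest interaction p adjusted over the list alone was 0.484 (edgeR). On simulated counts, whose genes varied independently, the same test recovered 26% of genes whose response differed 2-fold and 76% of those that differed 4-fold. The real libraries deviate on many genes at once, so these shares do not tell what the test would recover here.

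A drought index summed up the response of each library, scored on 300 genes ranked in the other line. In NIL-WT-72 it was 0.991 ± 0.470 in drought and -0.991 ± 0.312 in water (SD, n = 3). In NIL-bri1-72 it was 0.887 ± 0.329 in drought and -0.887 ± 0.153 in water (SD, n = 3). Each droughted library lay above each watered library of its line (exact permutation p = 0.1 in each line, two-sided, the lowest that 3 against 3 allows). The droughted libraries were spread out: NIL-WT-72 replicates 1, 2 and 3 scored 1.38, 1.13 and 0.469, and NIL-bri1-72 replicates 1, 2 and 3 scored 0.680, 0.715 and 1.27. Watered NIL-WT-72 replicates 1, 2 and 3 were spread as well, at -0.665, -1.02 and -1.29. On the pooled index of the 266 genes, drought minus water was 2.39 in NIL-WT-72 and 2.27 in NIL-bri1-72. The difference between the lines was -0.115 (SE 0.418, 95% interval from -1.08 to 0.849 from the pooled within-group variance), with an exact permutation p = 0.77 over 400 relabelings of the lines within regimes. With each library left out it ranged from -0.417, without NIL-WT-72 drought replicate 3, to 0.0815, without NIL-WT-72 drought replicate 1, so its sign is not fixed by these libraries.

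**Figure D4:**
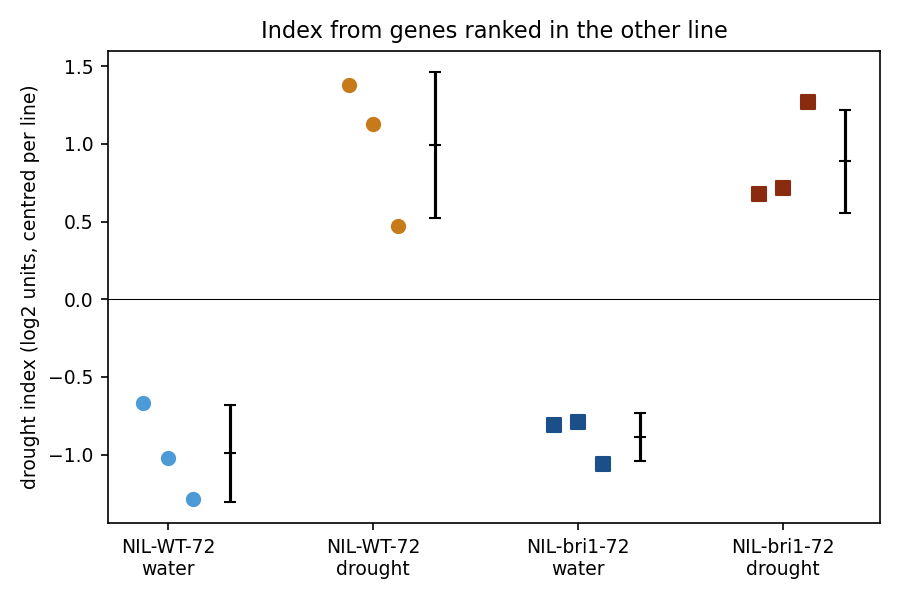
Drought index per library (log2 units, centred per line) from genes ranked by drought p in the other line, with 1 point per library and the group mean ± SD beside them (n = 3 per group). All droughted libraries lie at 0.469 or above and all watered libraries at -0.665 or below.

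The difference between the lines was tested in each regime. With 1 line per genotype it cannot be credited to the receptor mutation alone, since near-isogenic lines can differ in other segments too. Between NIL-bri1-72 and NIL-WT-72 0 genes passed by edgeR in water, where 1091 genes, 5.24% of those tested, had an unadjusted p below 0.05. In drought 0 passed, and 515 genes had such a p, 2.47% of those tested. Averaged over both regimes 0 genes passed by edgeR and 1351 had an unadjusted p below 0.05, 6.49% of those tested. Chance gives a share of 0.05, so the count in water is near chance and that in drought is below it. DESeq2 called 4 genes in water, 1 in drought and 32 averaged over both regimes, and limma voom called 0 in each. The 4 genes called by DESeq2 in water are named after their values were seen. Sobic.006G209000 and Sobic.010G061900 were higher in NIL-bri1-72, with log2 fold changes of 0.72 (SE 0.15) and 0.70 (SE 0.15) and DESeq2 adjusted p of 0.0116 and 0.0205. Sobic.002G261000 was lower, with a log2 fold change of -1.52 (SE 0.32, DESeq2 adjusted p = 0.0116). By edgeR the adjusted p of each of these genes was 0.888, and over all alternative settings it ranged from 0.0116 to 1.00 for these 3 genes.

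Sobic.007G154300 on chromosome 7 was the gene called by DESeq2 in both regimes. It was at 2.38 ± 0.513 CPM in NIL-bri1-72 and 6.16 ± 1.26 CPM in NIL-WT-72 in water, and at 4.97 ± 0.532 and 11.1 ± 2.51 CPM in drought (SD, n = 3). Each NIL-bri1-72 library lay below each NIL-WT-72 library of the same regime, 6 of 6 libraries. The gene had the lowest edgeR p of the averaged genotype contrast and was chosen for it, which favours such a separation. The log2 fold change was -1.39 in water (DESeq2 adjusted p = 0.00103) and -1.16 in drought (DESeq2 adjusted p = 0.0208). By edgeR the adjusted p was 0.888 in water, 1.00 in drought and 0.151 averaged over both regimes, at -1.27 (SE 0.16). Over all alternative settings the adjusted p ranged from 0.00103 to 1.00 in water, from 0.0208 to 1 in drought and from 4.97e-09 to 0.997 for the average. The replicates of the lines did not overlap for 10.4% of genes in water and for 6.69% in drought, where chance gives 10%.

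The genotype log2 fold changes in water and in drought, which share no library, correlated across genes, which are not independent replicates, with Pearson r = 0.399 and Spearman rho = 0.354. Without NIL-WT-72 drought replicate 3 the correlation was 0.162, and without any other single library it was between 0.303 and 0.445. Because 0 genes passed in both regimes, the planned test of where along the chromosomes the lines differ had no genes to place.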

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

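The averaged contrasts, the voom fits with library quality weights, the block within the 6 libraries compared, the fit without 2 NIL-WT-72 libraries and the correlation of genotype effects were added after the data had been examined. With every library thinned to the smallest total, edgeR called 260 genes for averaged drought, 8 for drought in NIL-WT-72 and 0 in the other contrasts. The edgeR count for drought in NIL-WT-72 was 3, and it was 305 by DESeq2, 1 by voom, 1 with only the libraries compared, 309 with quality weights, 27 with the replicate block within those 6 libraries and 200 without NIL-WT-72 water replicate 1 and drought replicate 3. For NIL-bri1-72 the count of 0 became 202, 0, 4, 1, 0 and 16 under the same alternatives in that order. The replicate block over all 12 libraries gave 2 genes in NIL-WT-72, 0 in NIL-bri1-72, 0 in each genotype contrast and the interaction and 230 for averaged drought. Of those 230 genes, 182 were among the 266 called without a block. In NIL-bri1-72, treated as paired, the block left 0 at 0 over 12 libraries and took 4 to 0 within its 6. There the adjusted p of Sobic.005G161100 went from 0.0482 to 0.0545. In NIL-WT-72 the same-number correlations were 0.0940, 0.219 and 0.270, so the first narrowly misses the bound of 0.1 and pairing was not assumed there. Replicate 1 did not correlate best with its own number (0.0940 against 0.121 for another), and replicates 2 and 3 did. Between the lines the same-number correlations ranged from -0.330 to 0.0998. The block over 12 libraries gives each replicate number an effect shared by both lines, which these values do not bear out. No block within each line was fitted for averaged drought, so its count does not account for the pairing treated as present in NIL-bri1-72.

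Averaged drought gave 266 genes, and 1023 by DESeq2, 997 with quality weights, 933 without the 2 libraries and 139 with a log2 fold change of at least 1. The 2 libraries had the drought index nearest to 0 in their groups (-0.665 and 0.469), so leaving them out widens the drought difference by construction. The genotype counts of 0 became 4 in water, 1 in drought and 32 averaged by DESeq2, and stayed at 0 under the other alternatives run, and the interaction stayed at 0 under all of them. The overlap of drought calls between the lines was 0, and 117 by DESeq2, 1 with quality weights and 13 without the 2 libraries. Leaving out each library gave 0 to 55 genes in NIL-WT-72, 0 to 14 in NIL-bri1-72, 41 to 695 for averaged drought and 0 to 11 for the overlap. The cause of these differences between tests was not tested. The correlation of the drought effects was 0.607, and 0.679 with the stricter filter, 0.671 by voom, 0.660 with the replicate block, 0.698 with quality weights, 0.679 with the block within the libraries compared and 0.658 without the 2 libraries. It ranged from 0.495 to 0.656 with each library left out. The correlation of the genotype effects was 0.399, and 0.284 with quality weights, 0.0634 without the 2 libraries and 0.162 to 0.445 with each library left out. On the pooled drought index the lines differed by -0.417 to 0.0815 with each left out. The 9 named genes kept their direction under all alternatives run. Of the calls in NIL-WT-72, Sobic.009G004900 lost its call under 8 and Sobic.005G161100 under 11 of 23 alternatives, with adjusted p up to 0.334. DESeq2 size factors and no filter moved no count by 1.5 times, and no filter removed no gene, so that setting says nothing on stability. The gene list tests and their alternatives were not run, since no identifier was paired with a description.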

Other observations

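The adjacency of drought-called genes and, for the correlation of genotype effects, the splits, the thinning and the values without 1 or 2 libraries were tests chosen only after the result was seen. The window statistic along the chromosomes, run on the genotype contrast averaged over regimes, was chosen after no gene had passed in either regime. Genes called for averaged drought stood next to each other along the chromosomes. Of the 265 placed on chromosomes, 18 had as direct neighbour among the tested genes another called gene of the same direction, in 10 adjacent pairs of which 8 fell and 2 rose. Shuffled positions gave 3.41 such genes on average and 16 at most (permutation test, 10000 shuffles, p = 0.0001, the smallest they can give), which argues against chance placement. Neighbouring near-identical copies that share reads remain a possible explanation and were not tested, because no sequence was used here, and joint regulation of neighbours was not tested either.

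Regrouping the same libraries bears on chance. For averaged drought 1 of 100 splits, the real one, gave 266 genes or more. The highest other split drawn gave 116, which argues against chance for that count. The other splits were a random draw from those possible, so 116 need not be the highest of all. Splits of the interaction and of the lines averaged over regimes were drawn likewise. The averaged drought contrast was added after the data had been examined. The splits did not keep libraries of 1 replicate number together, although those of NIL-bri1-72 were treated as paired. For drought in NIL-WT-72 1 of 10 splits reached the real count of 3 and the highest other gave 0, and 10 splits are too few for a share under 0.05. The other counts were 0, which every split reaches, so their splits say nothing about chance. These were 10 of 10 for drought in NIL-bri1-72 and for the lines in water and in drought, with a highest other count of 0, and 100 of 100 for the interaction and for the lines averaged over regimes, with highest other counts of 0 and 1.

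The genotype effects in water and in drought ran together across genes, although no gene passed the edgeR threshold. Of 100 splits within regimes 1, the real one, reached the correlation of 0.432 from group means of log2 CPM, with 0.420 for the highest other split and a median of 0.148. This argues only narrowly against a chance division of the libraries. No splits were run without NIL-WT-72 water replicate 1 and drought replicate 3, whose placing in 1 line could itself be chance. With every library thinned to the smallest total the correlation was 0.383, against 0.399 before. Counts had already been scaled for library totals, so thinning could change it little. A difference in composition or quality that goes with depth would remain after thinning, so depth stays open. A chromosome segment that differs between the lines stays open: 40 of 100 splits reached the largest excess of 0.244 in windows of 100 genes (highest other split 0.371, shuffle permutation p = 0.217), whereas windows of 200 genes exceeded shuffled gene order (permutation p = 0.013), with 11 of 100 splits as large, and windows of 50 genes did not (permutation p = 0.847, 79 of 100 splits). The correlation was 0.162 without NIL-WT-72 drought replicate 3, 0.303 to 0.445 without any other single library and 0.0634 without that library and NIL-WT-72 water replicate 1, so a deviation shared by these 2 libraries and an effect of the receptor mutation both stay open.

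Droughted replicates differed in how far they had moved along the drought direction, which is a candidate explanation for the low counts within each line. If plants responded to drought by degrees, deviations of libraries from their group mean would line up with the drought effect of the other line. Their mean absolute correlation was 0.184, and 4 of 100 splits of the other line's libraries, the real one included, reached it, with a highest of 0.189 and a median of 0.151. The margin is small. The mean was taken over watered as well as droughted libraries, and over the sizes of correlations whatever their sign. With edgeR drought effects, single correlations ran from -0.171 to 0.198 in watered libraries and from -0.313 to 0.372 in droughted ones. Watered libraries had no drought response to grade. The result therefore does not tell a graded response from other variation between libraries. Library depth cannot be told apart from a graded response with 12 libraries. Within groups, depth and the index correlated with Pearson r = 0.497 (exact permutation p = 0.106 over 1296 orders within groups) and Spearman rho = 0.503 (exact permutation p = 0.113), and r was 0.602 without the 2 libraries farthest from the median depth.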
